A study of Homo sapiens with 6 samples.

How the data were processed

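RNA was measured in HCT116 cells, a human colon cancer line, after treatment with an siRNA against ADNP (siADNP) or a control siRNA (siControl), with 3 libraries in each group. Per the labels' protocols, total RNA was purified with Trizol and treated with a DNase that digests double-stranded DNA, and libraries were made from total RNA with a Nugen whole-transcriptome kit; the sources used here mention no poly(A) selection. The series' design text calls the 3 samples of a group biological replicates and does not say whether they came from separate cultures or transfections, so p-values measure the spread between these samples, part of which may be technical.

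The main table holds counts of reads per gene symbol, as the authors deposited them, with no normalization. Per the submitters' processing notes, the reads were processed with STAR, HTSeq and DESeq2 on the hg19 genome build, with no versions given. The gene annotation and the strand setting of the counting are not given in the sources used here, so reads of overlapping and antisense genes may not be separated. The second table holds deposited values on a log2-like scale. They correlated with a variance-stabilizing transformation recomputed with DESeq2 from the counts with r = 1 across genes and libraries, and the largest difference was 0.0148. In these log2 values every gene at 0 in all libraries sits at the floor of 7.13, and differences between groups are shrunken, with a slope of 0.687 on the log2 differences of well covered genes. They were used only in an alternative test.

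The count table lists 23368 symbols, and 17978 have at least 1 read. Lines that name no gene were left out of library sizes and tests. Of all reads in the table, the no-feature line took 53.5% to 55.7% per library, reads without a unique alignment 17.4% to 17.9%, and ambiguous reads 0.455% to 0.500%, while the lines for unaligned and low-quality reads were 0. Reads assigned to genes made up 26.4% to 28.3%. Spreadsheet software had turned 14 symbols into dates, and these genes carry no usable name. Of the symbols, 19863 were current RefSeq symbols and 2138 were an older name of a single current symbol. GC content and transcript length came from the longest transcript of each matched gene in a GENCODE annotation of a newer build. They were available for 97.0% of tested genes, and no coordinates are given, because the builds differ.

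Genes were tested with edgeR 4.0.16 in R 4.3.3, with TMM scaling, filterByExpr (minimum count 10), glmQLFit and glmQLFTest, siADNP minus siControl, two-sided, with Benjamini-Hochberg adjustment. A gene was called at an adjusted p under 0.05. Some genes and 1 list that were tested are not reported here, and counts over all genes and lists include them. Standard errors of log2 fold changes are the log2 fold change divided by the square root of the F statistic. Levels are CPM computed here with TMM scaling from the deposited counts. Gene lists were tested with camera (limma 3.58.1) against all other tested genes, with a preset inter-gene correlation of 0.01, and adjusted over the 22 lists and families with at least 5 tested genes. The same test with the correlation estimated from the data and fry, which asks whether the members move on balance in 1 direction, were run beside it. Shares of reads were compared by an exact permutation test, whose smallest two-sided p is 0.1 for 3 libraries against 3. Figures were drawn with matplotlib 3.10.9.

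The comparison, the lists and the rule for naming genes were fixed before the data were examined. The rule takes ADNP, the 12 largest rises and the 12 largest falls among called genes with a mean of at least 5 CPM and no overlap between the groups, leaving out symbols that begin with LOC or LINC, symbols in the form of clone or accession numbers with the prefixes RP, AC, AL or AP, and small RNAs, the 5 genes with the smallest p in each direction, and up to 4 members of each list with the smallest p. The lists cover WNT targets, WNT ligands and receptors, stem markers, colon differentiation, epithelial junctions, mesenchymal genes, S phase and mitosis, replication histones, interferon response, NF-kB, integrated stress and unfolded protein response, ERK targets, TGF-beta and BMP, neuronal genes, endoderm and mesoderm transcription factors, ADNP partners, cholesterol synthesis, hypoxia, ribosomal proteins, mitochondrially encoded genes, nuclear non-coding RNAs, and markers of fibroblasts and blood cells. Zinc finger genes named ZNF with a number formed a further family. Genes named outside the rule, after their values were seen, are INSIG1, XBP1, DNAJB9, BMI1, HIST1H2BB, HIST1H3C, HIST1H4H, MYC, JUN, DKK1, FOSL1, WNT9A, FZD3, LGR5, ASCL2, OLFM4, SMOC2, HOPX, ALDH1A1, CD44, TNFRSF19, COL1A2, COL3A1, DCN, LUM, KRT19, OVOL1, CYR61, CDKN2B, TGIF1, SMARCA2, SMARCE1 and RBBP7.

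No 2 libraries held identical counts. The chi-square per degree of freedom over genes lay between 1.80 and 3.04 for pairs within a group and between 6.63 and 8.63 for pairs across groups, so each library counted as a separate sample. The libraries held 7396771 to 10265175 gene reads. On counts simulated from the real means, library sizes and dispersions with added changes, the edgeR test of siADNP against siControl recovered 48.0% of the genes changed by 1.25-fold, 90.0% of those changed by 1.5-fold and 100% of those changed by 2-fold or 3-fold, over 12342 genes, and 4.52% of its calls were false. The changed genes, 50 per fold change, all had a control mean of at least 5 CPM, so recovery of less abundant genes was not simulated. They were a far smaller share than the 28.3% of tested genes called in the data. With a simulated GC trend and no changed gene, 231 genes were called without an offset and 1 with the GC offset, over 12489 genes.

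The alternatives were other scalings (DESeq2's size factors in edgeR, upper quartile, library totals), other tests (DESeq2 1.42.0 Wald, limma-voom, limma on the deposited log2 values, glmTreat against 1.2-fold), an adjusted p under 0.01, no filter or a filter of 1 CPM in 3 libraries, the replicate number as a block, an offset that removes a smooth trend on GC content or on length in each library, with and without the block, and leaving out each library.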

Results

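Gene expression was measured by RNA sequencing in HCT116 cells, an established colon cancer line known to carry an activating mutation in CTNNB1. The cells had been treated with an siRNA against ADNP, a chromatin-associated zinc finger and homeodomain protein, or with a control siRNA, and the comparison asks which transcripts change when ADNP is depleted. Each group held 3 libraries. Reads assigned to genes numbered 7787046, 8726017 and 7396771 in the siADNP libraries and 8991290, 10265175 and 8282290 in the siControl libraries.

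ADNP mRNA itself was depleted in every siADNP library. Its level was 46.7, 55.3 and 59.8 CPM in the siADNP libraries and 171, 155 and 167 CPM in the siControl libraries, with means of 53.9 ± 6.62 and 164 ± 8.24 CPM (SD, n = 3 each). ADNP thus stood at 32.9% of the control level, with a log2 fold change of -1.61 ± 0.07 (SE) and an adjusted p of 2.62e-20 in edgeR's quasi-likelihood test, the smallest p of all genes tested. The labels and the target's level match in all 6 libraries.

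Of 12489 genes tested, 1824 were higher and 1714 lower with siADNP at an adjusted p under 0.05 (edgeR), and most of these differences were small. The median absolute log2 fold change of called genes was 0.32. At least 1.5-fold changes numbered 488 rises and 135 falls, and at least 2-fold changes 123 rises and 23 falls. The genes with 2-fold rises gained a median of 2.08 CPM, so many of them were weakly expressed. The groups did not overlap in 5099 genes, 40.8% of those tested, where chance gives 10%. The first principal component, with 52.1% of the variance, separated the groups. DESeq2's Wald test called fewer genes, 1106 higher and 1079 lower. The genes called higher had a median GC content of 54.0% and those called lower 43.0%, against 48.6% among genes not called.

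Among called genes with a mean of at least 5 CPM and no overlap between the groups, the largest rise was in PALM3, a paralemmin, which rose 3.99-fold, from 6.24 ± 1.04 to 24.8 ± 4.26 CPM (SD, n = 3; edgeR adjusted p = 1.25e-13). NES, the intermediate filament protein nestin of neural progenitors, rose 3.02-fold, and CNTNAP1, a contactin-associated protein of axons, 2.96-fold. MRC2, an endocytic collagen receptor, rose 3.61-fold. FLJ22184, SUSD2, ORAI2, MAP3K12 and GLI2, the last a transcription factor of Hedgehog signalling, rose by 3.22-fold, 2.82-fold, 2.60-fold, 2.59-fold and 2.51-fold. Among more abundant transcripts, CHPF, a chondroitin polymerizing factor, rose from 55.5 ± 3.88 to 138 ± 6.43 CPM (SD, n = 3), a log2 fold change of 1.32 ± 0.06 with an adjusted p of 9.30e-19 in edgeR. The adhesion molecule MCAM and the retinoic acid carrier CRABP2 rose 2.42-fold and 2.36-fold. TNS4 and TLN1, which encode tensin 4 and talin 1 of integrin adhesions, rose 2.09-fold and 1.90-fold.

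Under the same conditions the largest fall was in CPA4, a carboxypeptidase, whose mean dropped from 51.9 ± 1.46 to 16.1 ± 0.717 CPM (SD, n = 3), with a log2 fold change of -1.69 ± 0.09 and an adjusted p of 1.45e-17 (edgeR). ANGPT2, a secreted ligand of the TIE2 receptor, stood at 33.9% of control and TFPI, an inhibitor of coagulation, at 45.7%. CDKN1A, the cell cycle inhibitor p21, stood at 47.0% of control (log2 fold change -1.09 ± 0.06, adjusted p = 1.36e-16, edgeR). RPS27L, PLK2 and SFN fell with log2 fold changes of -0.68, -0.57 and -0.52. CEBPD, SEMA3C, ACTA2 and BIRC3 stood at 47.7%, 47.9%, 48.7% and 50.03%. BANK1, PDGFA and KANSL1L stood at 52.2%, 52.6% and 55.8%. ANXA1, far more abundant, fell from 342 ± 9.80 to 202 ± 19.7 CPM (SD, n = 3).

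**Figure D1:**
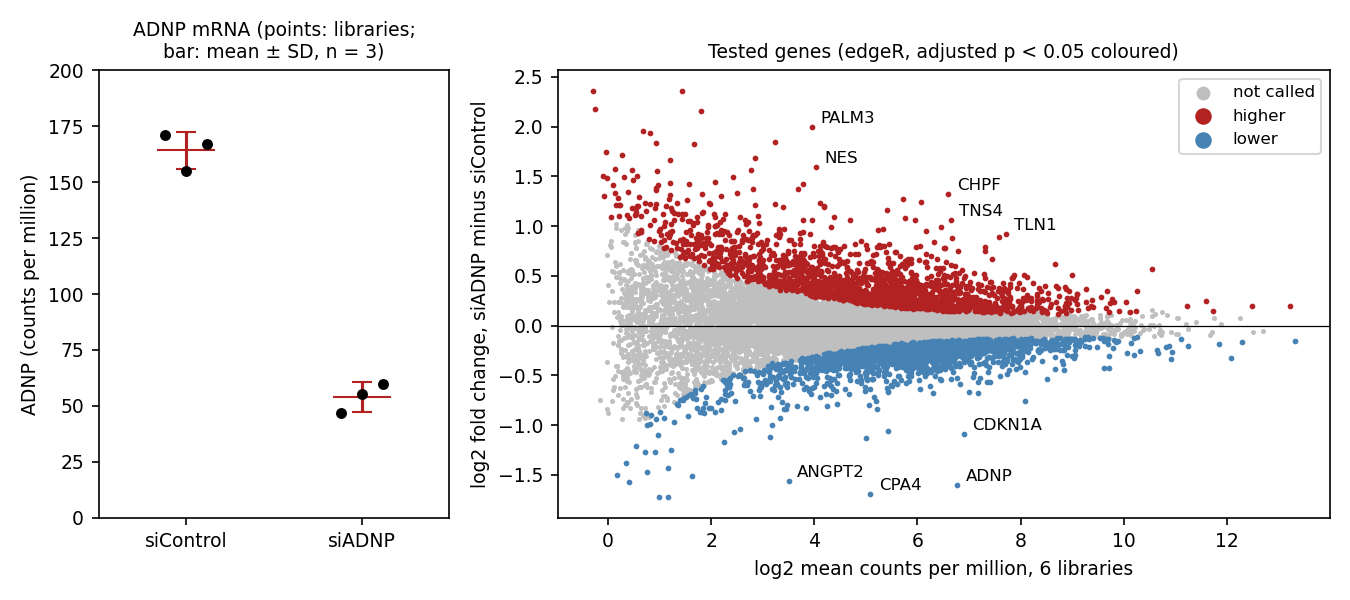
Left, ADNP level in CPM in each library, with the mean and SD of 3 libraries per group. Right, log2 fold change (siADNP minus siControl) against log2 mean CPM of each tested gene, with called genes in red (higher, 1824) and blue (lower, 1714); CPA4, ADNP and ANGPT2 lie lowest and PALM3 highest among the labelled genes.

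Genes of cholesterol synthesis and other SREBP targets rose. Of 33 tested, 21 rose, 1 fell and 11 did not pass (23 rose and 1 fell when adjusted over the list alone), with a median log2 fold change of 0.22. The sterol methyl oxidase MSMO1 rose with a log2 fold change of 0.74 ± 0.07 (adjusted p = 4.42e-10, edgeR) and the sterol carrier STARD4 with 0.65. Squalene synthase FDFT1 rose with 0.48 and fatty acid synthase FASN with 0.35, from 1076 ± 23.2 to 1374 ± 46.2 CPM (SD, n = 3). INSIG1, an inhibitor of SREBP processing and itself an SREBP target, was the member that fell, with a log2 fold change of -0.23. Camera called the list higher (adjusted p = 2.25e-10), with an adjusted p of 0.0548 with an estimated correlation.

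Genes of the integrated stress and unfolded protein responses rose as a list, with 19 of 33 tested members higher, 2 lower and 12 not passing (21 rose and 2 fell when adjusted over the list alone). The serine synthesis enzymes PHGDH and PSPH rose with log2 fold changes of 0.75 ± 0.05 (adjusted p = 2.38e-13, edgeR) and 0.41. The cystine transporter SLC7A11 and the endoplasmic reticulum isomerase PDIA4 both rose with 0.38. The members that fell were XBP1, a transcription factor of the unfolded protein response, and its chaperone target DNAJB9, both with -0.42. Camera gave an adjusted p of 1.45e-07, and 0.323 as adjusted p with an estimated correlation.

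**Figure D2:**
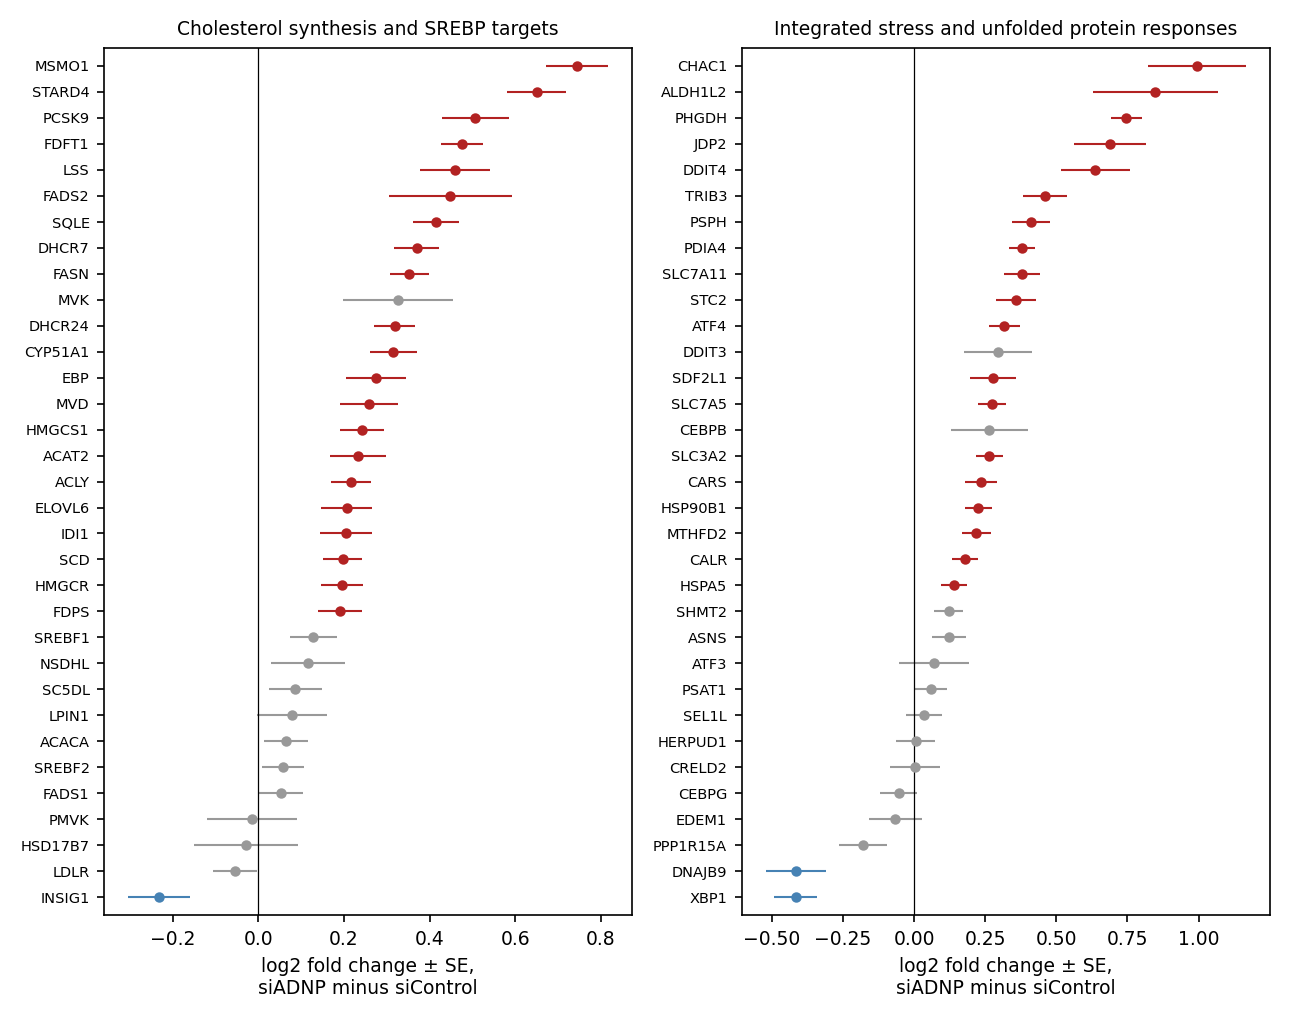
Log2 fold change with its SE (siADNP minus siControl, 3 libraries each) of each tested cholesterol or SREBP gene (left, 33 genes) and each tested gene of the stress and unfolded protein responses (right, 33 genes). Red and blue mark genes called higher and lower, and grey those that did not pass; 21 cholesterol genes rose while INSIG1 fell, and 19 stress genes rose while XBP1 and DNAJB9 fell.

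Targets of WNT and beta-catenin moved in both directions. Of 32 tested, 13 rose, 6 fell and 13 did not pass (14 rose and 7 fell when adjusted over the list alone), and camera did not call the list (adjusted p = 0.0902, median log2 fold change 0.15), while fry, which does not compare the list with other genes, called it higher (adjusted p = 0.000310). The Notch ligand JAG1 rose with a log2 fold change of 0.66 ± 0.07 (adjusted p = 4.05e-09, edgeR), the receptor EPHB2 with 0.59, the adhesion molecule L1CAM with 0.97 and the feedback inhibitor AXIN2 with 0.54. CCND1, which encodes cyclin D1, fell with -0.43 ± 0.05 (adjusted p = 6.42e-09, edgeR). Among the other members that fell were JUN, DKK1, FOSL1 and MYC, with -0.43, -0.26, -0.22 and -0.13. LGR5 was not testable, with 1 read over the 3 siADNP libraries and 0 over the 3 siControl libraries.

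WNT ligands and receptors included 7 rises, 3 falls and 10 members that did not pass among 20 tested (9 rose and 3 fell when adjusted over the list alone). The camera test just missed the threshold (adjusted p = 0.0549, median log2 fold change 0.24), and passed it without siADNP replicate 1 (0.0300), without siADNP replicate 3 (0.0329) or without siControl replicate 3 (0.0225). It also passed with no filter (0.0332), with a filter of 1 CPM in 3 libraries (0.0395) and with the GC offset and the replicate block (0.0464), over a range of 0.0225 to 0.338 in the camera alternatives. The receptor kinase PTK7, the co-receptor LRP6 and the ligand WNT7B rose with log2 fold changes of 0.48, 0.34 and 0.95. The receptors FZD6 and FZD3 fell with -0.26 and -0.28. The ligand WNT9A, weakly expressed, fell with -1.27, from a mean of 2.33 CPM with siControl to 0.956 CPM with siADNP. Stem markers were called higher (adjusted p = 0.00778, and adjusted p = 0.165 with an estimated correlation), with 8 of 16 tested rising, 1 falling and 7 not passing, the same when adjusted over the list alone. Of the rises, EPHB2, AXIN2, SOX9 and CD44 are also on the list of WNT targets, as is TNFRSF19, which did not pass. ALCAM rose with a log2 fold change of 0.43 and SOX9 with 0.29, while BMI1, a Polycomb protein, fell with -0.61. The call covers 16 of the 22 listed stem markers, and the others had too few reads to test. ASCL2, OLFM4, SMOC2 and HOPX had 0 reads in both groups. LGR5 had 1 read with siADNP and 0 with siControl, and ALDH1A1 had 0 and 2.

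**Figure D3:**
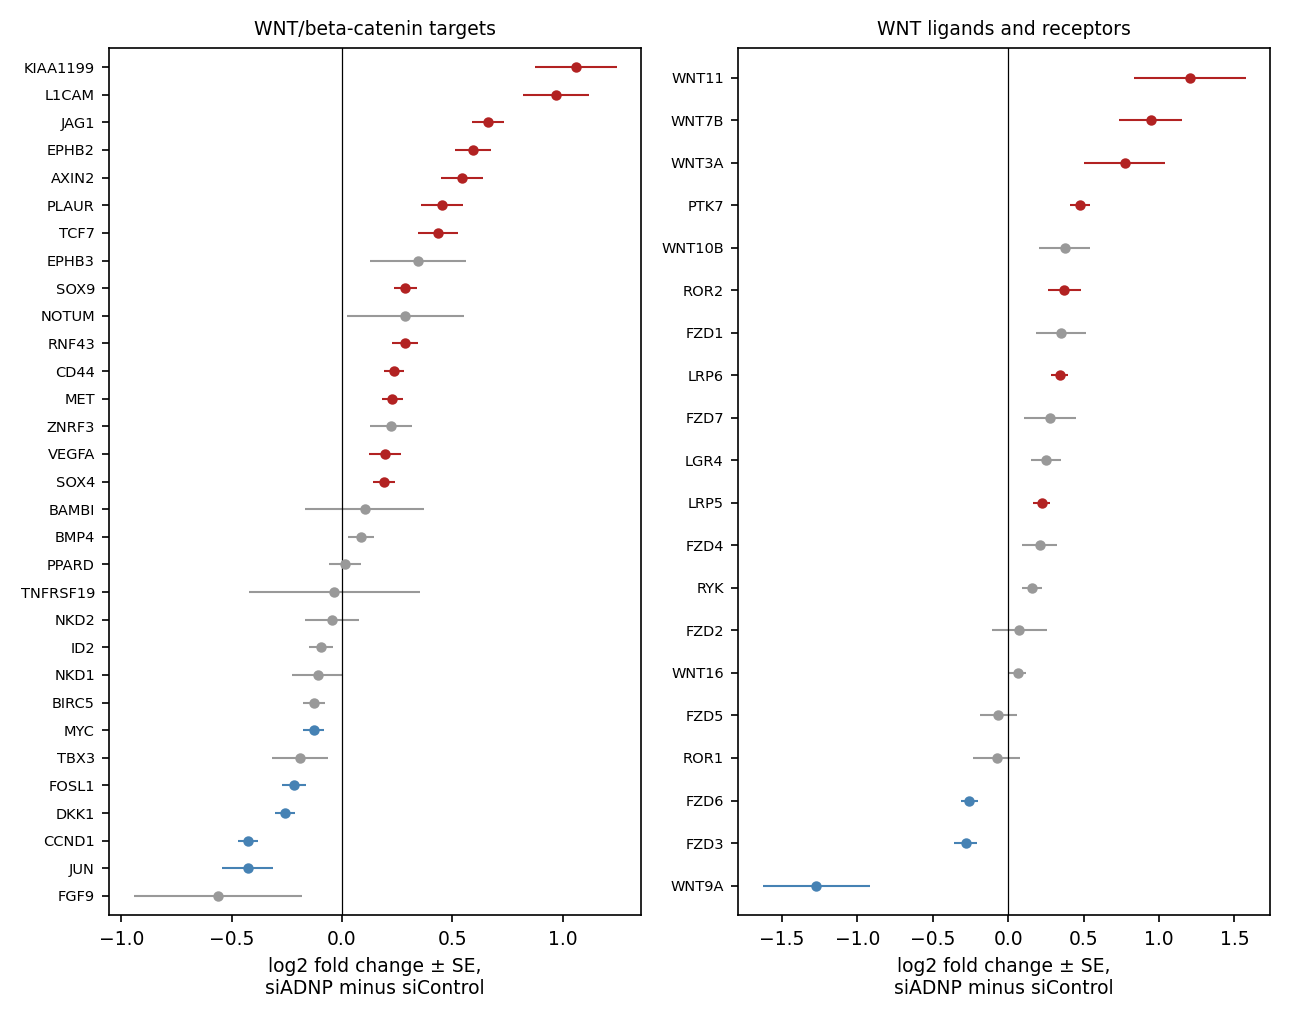
Log2 fold change with its SE (siADNP minus siControl, 3 libraries each) of 31 of the 32 tested WNT targets (left) and the 20 tested WNT ligands and receptors (right). Red, blue and grey mark genes called higher, called lower and not passing; 13 targets rose, and CCND1 and JUN lie lowest among those that fell.

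Replication-dependent histone genes rose in small steps. Of 39 tested, 26 rose, 3 fell and 10 did not pass (26 and 3 when adjusted over the list alone), with a median log2 fold change of 0.23. HIST1H1C rose with 0.36 ± 0.05 (adjusted p = 2.16e-07, edgeR), HIST2H2AC with 0.43, HIST1H2AM with 0.36 and HIST1H4C with 0.33. HIST1H2BB, HIST1H3C and HIST1H4H fell with -1.10, -0.93 and -0.25. These genes have near-identical copies, so values of single members are uncertain. Camera gave an adjusted p of 1.45e-07, and 0.354 as adjusted p with an estimated correlation. Fry did not call the list (adjusted p = 0.0613). Genes of S phase and mitosis were not called as a list (adjusted p = 0.157, median -0.06), with 4 rises, 12 falls and 33 not passing among 49 (5 rose and 13 fell when adjusted over the list alone). The mitotic transcription factor FOXM1 and the kinesin KIF11 rose with 0.35 and 0.33, and CCNE2 and CDC25A, which promote entry into S phase, fell with -0.65 and -0.35.

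Neuronal genes were called higher (camera adjusted p = 6.10e-05, and adjusted p = 0.0692 with an estimated correlation), with 9 of 17 tested rising, none falling and 8 not passing, the same when adjusted over the list alone. Besides NES and L1CAM, the glutamate receptor subunit GRIN1 rose with a log2 fold change of 1.02 ± 0.18 (adjusted p = 4.35e-05, edgeR) and the stathmin STMN3 with 0.74. Mesenchymal genes gave 6 rises, 2 falls and 9 not passing among 17 (7 rose and 2 fell when adjusted over the list alone). S100A4, COL6A1 and ITGA5 rose with 0.86, 0.46 and 0.37, while ACTA2 and CYR61 fell with -1.04 and -0.56. Camera called this list narrowly (adjusted p = 0.0464, and adjusted p = 0.257 with an estimated correlation). The call ended with the GC offset (adjusted p = 0.107), without siADNP replicate 3 (0.0697) and without siControl replicate 2 (0.0978), in a range up to 0.257 over the camera alternatives. It ended too with upper-quartile scaling, library totals, no filter and the length offset.

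Epithelial junction genes were not called as a list (adjusted p = 0.543), with 5 rises, 3 falls and 19 not passing among 27 tested, the same when adjusted over the list alone. Claudin CLDN3, desmoplakin DSP and TJP3 rose with log2 fold changes of 1.31, 0.50 and 0.51, and MARVELD2, OVOL1 and KRT19 fell with -0.30, -0.41 and -0.15. Of 7 testable markers of differentiated colon epithelium, 2 rose, 1 fell and 4 did not pass, the same when adjusted over the list alone (adjusted p = 0.514). DPP4 rose with 0.46. CA2 rose with 0.31 and MALL fell with -0.18, but neither passed in DESeq2's Wald test or without siADNP replicate 3 (adjusted p = 0.0723 for CA2 and 0.115 for MALL), siControl replicate 1 (0.0778 and 0.0852) or siControl replicate 2 (0.0877 and 0.342), nor MALL without siADNP replicate 2 (0.0666) or with upper-quartile scaling (0.0725). TGF-beta and BMP genes gave 4 rises, 2 falls and 13 not passing among 19, the same when adjusted over the list alone (adjusted p = 0.196). TGFB1 rose 2.12-fold (log2 fold change 1.09 ± 0.07, adjusted p = 1.84e-14, edgeR), BMP7 with 0.93, SMURF2 with 0.33 and TGIF1 with 0.19, and ID1 and CDKN2B fell with -0.45 and -0.63. Of 15 transcription factors of endoderm and mesoderm, 2 rose and 13 did not pass, the same when adjusted over the list alone (adjusted p = 0.196). FOXC1 rose with 0.26.

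The interferon response list was not called (adjusted p = 0.681), with 3 rises, 1 fall and 27 not passing among 31 (2 rose and 0 fell when adjusted over the list alone). TAP1, a peptide transporter of antigen presentation, rose with a log2 fold change of 0.35. EIF2AK2 rose with 0.17 and SAMD9 fell with -0.27, but neither passed in DESeq2's Wald test or without siADNP replicate 1 (adjusted p = 0.150 and 0.116) or siControl replicate 3 (0.190 and 0.0951). EIF2AK2 did not pass without siControl replicate 1 (0.0791) or with no filter (0.0516). SAMD9 did not pass without siADNP replicate 3 (0.120) or siControl replicate 2 (0.0743), with the GC offset (0.154, and 0.167 with the replicate block) or with upper-quartile scaling (0.0538). NF-kB and inflammatory genes gave 3 rises, 3 falls and 12 not passing among 18 (3 rose and 4 fell when adjusted over the list alone; adjusted p = 0.657). Their median was 0.05, their mean -0.00457 and the camera direction downward. ICAM1 rose with 0.92, and BIRC3, the growth factor EREG and NFKB1 fell with -0.999, -0.42 and -0.31. ERK targets gave 7 rises, 8 falls and 16 not passing among 31, the same when adjusted over the list alone (adjusted p = 0.9998). Their median was 0.01 and mean 0.04, against a downward camera direction. PHLDA1 and DUSP5 rose with 0.49 and 0.42, and CCND1 and EREG fell with -0.43 and -0.42. Hypoxia and glycolysis genes gave 8 rises, 2 falls and 18 not passing among 28, the same when adjusted over the list alone (adjusted p = 0.257), with ALDOC, P4HA2 and NDRG1 rising with 0.63, 0.48 and 0.32.

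Among ADNP and the proteins described in complexes with it, 10 rose, 4 fell, ADNP included, and 25 did not pass of 39 (12 rose and 4 fell when adjusted over the list alone), and the list was not called (adjusted p = 0.657). ARID1B of the SWI/SNF complex, CHD3 and GATAD2B of the NuRD complex rose with log2 fold changes of 0.43, 0.39 and 0.34. SMARCA2, SMARCE1 and RBBP7 fell with -0.43, -0.22 and -0.18. Zinc finger genes of the ZNF family were not called as a group (adjusted p = 0.452), with 26 rises, 37 falls and 284 not passing among 347 tested (21 rose and 28 fell when adjusted over the list alone). Their median log2 fold change was -0.02, and 0.00135 with upper-quartile scaling. ZNF624, ZNF263, ZNF678 and ZNF721 fell with -0.84, -0.63, -0.51 and -0.46.

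Ribosomal protein genes gave no rise, 10 falls and 55 not passing among 65 tested (3 fell when adjusted over the list alone; adjusted p = 0.157), with RPS4X, RPS12 and RPS20 at -0.28, -0.25 and -0.21. Many ribosomal protein genes have processed copies that share reads. The list test passed the threshold without siADNP replicate 1 (adjusted p = 0.00997) or replicate 3 (0.0142) and turned upward without siADNP replicate 2 (0.576), over a range of 0.00997 to 0.771 in the camera alternatives. Nuclear non-coding RNAs gave 3 rises, 5 falls and 10 not passing among 18, the same when adjusted over the list alone (adjusted p = 0.189, and 0.0300 without siADNP replicate 1, in a range up to 0.603). TUG1, SNHG5 and GAS5 fell with -0.39, -0.38 and -0.26, and RPPH1 rose with 0.24 but did not pass with the GC offset, where its log2 fold change was 0.11 (adjusted p = 0.0911, and 0.110 with the replicate block). No mitochondrially encoded gene was listed in the table. Of the fibroblast and smooth muscle markers, 3 were testable: DES rose (1.83, at 4.94 ± 1.58 against 1.38 ± 0.298 CPM; SD, n = 3), ACTA2 fell (-1.04) and COL1A1 did not pass (0.14). Of the blood cell markers, CD68 was testable and rose with 0.42 (adjusted p = 0.0366, edgeR). Its call ended in DESeq2's Wald test, with the GC offset (0.0749, and 0.0910 with the replicate block) and without siADNP replicate 1 (0.0704), 2 (0.0622) or 3 (0.0832) or siControl replicate 2 (0.0901) or 3 (0.114).

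**Figure D4:**
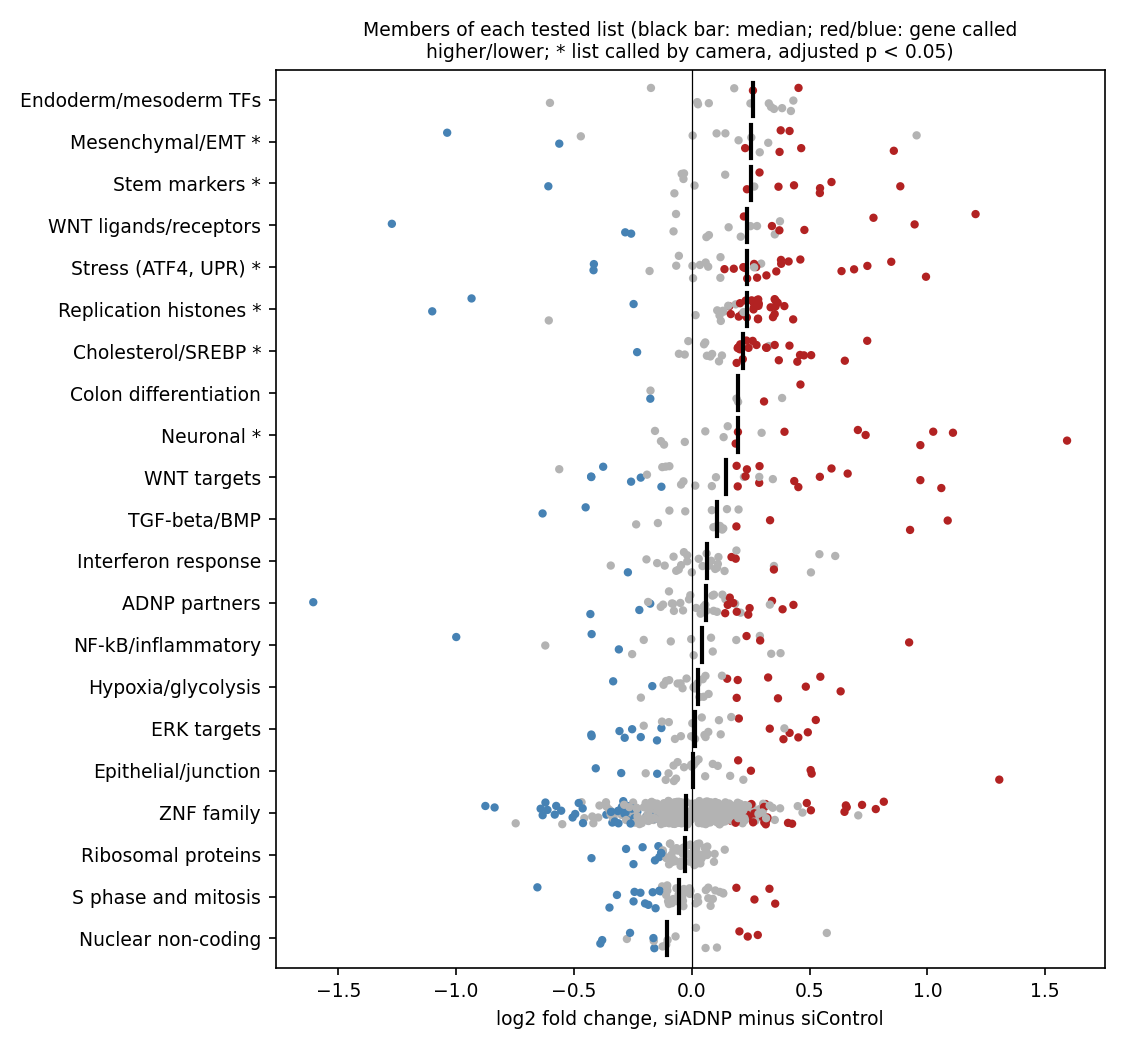
Log2 fold change (siADNP minus siControl) of every tested member of 21 tested lists and families, ordered by the median (black bar). Red and blue points are genes called higher and lower, and an asterisk marks the 6 of them called by camera at the preset correlation, all 6 higher.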

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

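The tests of fibroblasts and of unspliced RNA were chosen after their results were seen, and the test within a band of GC content was chosen after the result of the GC offset had been seen, though its prediction was written before its own value.

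Reads on the no-feature line, which were assigned to no gene, took a larger share in the siADNP libraries. They may include intronic or antisense reads of annotated genes, since the annotation and strand setting are not given. The no-feature line held 55.0% ± 0.660 of reads in the siADNP libraries and 53.8% ± 0.403 in the siControl libraries (SD, n = 3 each), higher in each siADNP library than in each siControl library. The exact permutation test gave a two-sided p of 0.1, the smallest that 3 against 3 allows.

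The count of 3538 called genes goes with a trend on GC content. Relative to the other libraries, expression rose with GC content in the siADNP libraries, by log2 values of 0.0560, 0.0339 and 0.0493 per 10 percentage points, and fell in the siControl libraries, with -0.0518, -0.0459 and -0.0416. Removing the trend left 75.7% of the 3480 called genes with a GC value called in the same direction, while the 847 lost genes went from a median absolute log2 fold change of 0.22 to 0.14. Against the trend as the whole cause, 26.6% of the 759 tested genes within 1 percentage point of the GC content where the trend is 0 were called, against 28.7% of all tested genes with a GC value, and against a difference in depth, 89.3% of the calls were made again after every library was thinned to 7396771 reads. For the lost genes a library effect and an effect of ADNP depletion cannot be told apart, since the trend follows the groups. For all called genes, ADNP depletion and any other effect of the siRNA cannot be told apart, since the series has no other group. Only the real 1 of the 10 splits of the 6 libraries called as many genes (highest other 0). These are too few splits for a share under 0.05.

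Rises of at least 2-fold outnumbered falls, 123 against 23, and the ratio of 5.35 (6.21 among genes with a GC value) was 4.59 with the GC offset, which argues against the GC trend as the whole cause. Fibroblasts are argued against by their abundant transcripts COL1A2, COL3A1, DCN and LUM, which held 3 reads together over the siADNP libraries, 0.125 CPM over library totals (exact Poisson upper 95% limit 0.367, counting error only), against a median rise of 2.08 CPM in the genes with 2-fold rises. Reads from genomic DNA stay open. The 393 olfactory receptor genes took a pooled share 0.921 times that of the control (exact Poisson 95% interval 0.863 to 0.983, counting error only). This met the bound set beforehand against genomic DNA. A larger share in every siADNP library, set beforehand as the sign of that cause, was not seen. But the libraries overlap, with 78.7, 61.7 and 69.9 CPM over library totals in the siADNP and 76.6, 77.0 and 73.2 in the siControl libraries. The bound, which took counting error alone, was thus too loose to decide. Reads from unspliced RNA stay open as well. The share of reads on the no-feature line was higher by 1.19 percentage points with siADNP (exact permutation p = 0.1, two-sided). A comparison of 3 against 3 cannot give a smaller p. An effect of ADNP depletion itself also stays open, as untested.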

How the results depend on the processing

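ADNP stayed lower and called under every alternative run for it, with a log2 fold change from -1.51 (without siADNP replicate 1) to -1.68 (without siADNP replicate 3). The numbers of genes higher and lower were 1106 and 1079 with DESeq2's Wald test, 1210 and 1064 at an adjusted p under 0.01, and 457 and 179 with glmTreat against 1.2-fold, which by construction asks for larger changes; the cause of the DESeq2 difference was not tested. Every other setting stayed within 1.5 times of the main counts. Leaving out single libraries gave 1470 to 1655 higher and 1307 to 1508 lower, and upper-quartile scaling 2096 and 1379. With the GC offset there were 1671 and 1535, of which 1415 and 1218 were shared with the main test.

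Same-numbered libraries did not deviate together (correlations of 0.0238, -0.0352 and -0.0290), so no shared effect of the number was seen. Whether same-numbered samples were handled together is not given in the sources used here. With the replicate block 1694 genes were higher and 1542 lower, and with the block and the GC offset 1549 and 1387.

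Of 105 called genes that the naming rule takes besides ADNP, 95 kept direction and call under every alternative run for single genes, which leaves out glmTreat, the adjusted p under 0.01 and limma on the deposited values, and 10 lost the call at least once, among them CA2, CD68, EIF2AK2, MALL, RPPH1, RPS10, SAMD9 and SLC2A1. HHEX passed only without siADNP replicate 3 and HNF4A only without siADNP replicate 2. COL1A1, not called, ranged from -0.0537 without siADNP replicate 2 to 0.235 without siADNP replicate 1; the cause was not tested.

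The number of lists called was 6 to 10 over the tests that left out a library. It went from 7 to 1 with an estimated correlation, and no list described here was called with it. The estimate was 0.385 for histones, 0.261 for stress genes and 0.0279 for cholesterol genes, above the preset 0.01. For stem markers, mesenchymal genes and neuronal genes it was -0.0236, -0.0116 and -0.0526, below the preset. A higher correlation thus cannot account for calls lost in these last lists. The cause was not tested for any list. The mesenchymal list also lost its call with upper-quartile scaling (adjusted p = 0.0625), library totals (0.0556), no filter (0.0962) and the length offset (0.0532), over a range up to 0.257, and the histone list with fry (0.0613). The ZNF family stayed uncalled throughout (0.340 to 0.755 with camera, 0.160 with fry). Among lists not called, directions turned for the epithelial list with the GC offset (adjusted p = 0.825, and 0.826 with the replicate block) and for the ERK list with DESeq2's size factors (0.994), upper-quartile scaling (0.913), library totals (0.978), the replicate block (0.930) and fry (0.902), and without siADNP replicate 1 (0.545) or siControl replicate 2 (0.567), within 0.545 to 0.810 over the tests that left out a library. The ribosomal protein list, over the same tests, ranged from 0.00997 to 0.576 and turned upward at the latter; the cause was not tested. Fry, which does not compare a list with other genes, called 10 lists, among them 4 that camera did not call, all higher: WNT targets (adjusted p = 0.000310), WNT ligands and receptors (0.0200), TGF-beta and BMP genes (0.0108) and endoderm and mesoderm factors (0.0296). On counts simulated at these library sizes and group sizes the test missed many of the smallest changes, so a gene that did not pass is not shown to be unchanged; how much of this is due to depth was not tested.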

Other observations

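The families below were formed from symbol stems and tested after the data were seen, over 142 families with at least 10 tested genes. As a background for their counts, 28.3% of all 12489 tested genes were called, 1824 higher and 1714 lower. Of 16 tested genes with TSPAN symbols, 7 rose and none fell, with a median log2 fold change of 0.28 (camera adjusted p = 0.00499, and 0.00528 with the GC offset). They encode tetraspanins, membrane proteins that organise receptors and integrins, but tetraspanins with other symbols were not part of this family. The TSPAN call was lost with an estimated correlation (camera adjusted p = 0.944). No family was called with it, and every family called at the preset correlation had this same adjusted p. The value thus does not tell these families apart. Of 12 genes with LRP symbols, most of them receptors related to the low-density lipoprotein receptor, 6 rose and 1 fell (adjusted p = 0.0269, 0.0534 with the GC offset, and adjusted p = 0.944 with an estimated correlation).

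Of 30 tested VPS genes, most of whose products sort proteins to endosomes and lysosomes, 7 fell and none rose, with a median of -0.13 (camera adjusted p = 0.00775, 0.0110 with the GC offset, and adjusted p = 0.944 with an estimated correlation). Of 16 ATG genes of autophagy, 6 fell and none rose, with a median of -0.18 (adjusted p = 0.0269, 0.0283 with the GC offset, and adjusted p = 0.944 with an estimated correlation). Of 11 annexin genes, 6 fell and 1 rose, with a median of -0.22 (adjusted p = 0.00897, 0.0283 with the GC offset, and adjusted p = 0.944 with an estimated correlation).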
